A study of Homo sapiens with 18 samples.

How the data were processed

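Total RNA of PC-3 cells from 3D culture was measured on 18 Illumina bead arrays of 47323 probes, 3 in each of 6 groups: scrambled, HSF1 or HSF2 siRNA, at day 5 or day 8. Per the labels, siRNA was given by reverse transfection at 13.3 nM, HSF1 was targeted with a mixture of siRNA constructs, and cells recovered for 48 h after transfection. The RNA was taken after the spheroids had been detached from the gel, by the same protocol for every group. The study's design text calls the triplicates biological replicates. The sample descriptions give 8 days of culture for all arrays, while the titles and source names give 5 or 8 days, and the latter were used.

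The deposited non-normalized table holds the intensity of each probe on each array, which the authors left on a linear scale, without background subtraction and without normalization between arrays. Beside each signal, per the file headers, stands a detection p-value of the probe, in steps that match a comparison with negative control beads. The deposited normalized table holds the intensity made comparable between arrays by the authors. Its columns share 1 distribution (sorted columns differ by at most 0.103%), with a lowest value of 118 and a median of 141, and each keeps the rank order of its own array (rank correlation 1, and at most 0.926 with any other array). The authors' processing notes name GenomeStudio, lumi and limma without versions, and which of them did which step is not given in the sources used here. The slide and position of each array are not given there either.

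Median signals of the arrays were 57.1 to 67.4 and mean signals 334 to 407. The 95th percentile was 25.2 to 31.3 times the median of undetected probes. No 2 arrays held identical values, and arrays of a group correlated with r of 0.963 to 0.993. The number of arrays limits the precision.

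The following choices were made before the data were examined: the groups, contrasts, tests, 23 gene lists, the rule for named genes and the main alternatives. Values were computed from the non-normalized table with R 4.3.3 and limma 3.58.1. Function neqc inferred the background from the detection p-values, added an offset of 16, normalized by quantiles and took log2. Probes were kept if detected (detection p under 0.05) on all 3 arrays of at least 1 group, which left 21181. Names came from the platform annotation through Entrez IDs for 30074 probes, its own symbols for 39, and the RefSeq accession for 1256. For 15946 probes there was no name and 8 matched several genes. For the 3509 genes with more than 1 kept probe, the probe with the highest mean was used. Unnamed probes were tested and are not named. This gave 16676 features and 12566 genes.

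A limma model of 6 group means was fitted to all 18 arrays (lmFit, then eBayes without a trend), and 9 contrasts were tested, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all features of a contrast. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists of a contrast, and with fry. A list needed 5 measured members. The results of 1 list and of 1 named gene are not reported here. The lists covered chaperones and the unfolded protein response, ATF4 targets, epithelial, mesenchymal, basal and luminal genes, adhesion, proteases, cell cycle, lipid synthesis, hypoxia, interferon, NF-kB, immediate early genes, TGF-beta and YAP, proteasome, ribosome, oxidative phosphorylation and markers of other cell types. Named genes were HSF1 and HSF2, the 6 largest rises and 6 largest falls past the threshold without overlap between arrays, and of each list up to 2 members past the threshold, or else 1 by value. List tests on the direct and day difference contrasts, the day contrasts in siRNA-treated arrays, the averages over both days and the fits with letters a and c alone were added after seeing the data.

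Effect correlations were set beside 100 simulated data sets with unchanged groups of independent arrays, without the letters, since both siRNAs share the control arrays. The letters were taken to pair samples in a contrast only if each of the 3 letters correlated by more than 0.1 between the groups. This held except for HSF2 siRNA day 5 against scrambled or HSF1 siRNA day 5. The day contrasts in siRNA-treated arrays and over all siRNA groups were not checked for it. The alternatives were: no background correction, scaling to equal medians, the authors' normalized table, no filter, a detection p under 0.01 on all arrays, every probe on its own, only the arrays compared, a replicate block, array weights, a trend in the variance prior, a fold minimum of 0.58 (log2) and leaving out each array.

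The steps were tested on simulated data of 16676 genes with 3 arrays a group. In the HSF2 siRNA day 5 contrast, 58.2% of 67 genes changed 2-fold were called, 14.9% of 67 changed 1.5-fold and 100% of 66 changed 4-fold, with 3 false calls among 118. In the scrambled day contrast, the shares were 53.7%, 13.4% and 98.5%, with 3 false calls among 113. The simulated arrays and genes were independent and had no letters, so these rates need not hold for the real arrays, where letter b stood apart.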

Results

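Gene expression was measured in PC-3 cells, an established human prostate cancer line, grown as spheroids in a laminin-rich gel. The cells had been transfected with a scrambled control siRNA, with siRNAs against HSF1 or with siRNA against HSF2, each at 13.3 nM, and were harvested after 5 or 8 days, which the labels do not date from transfection or from plating. HSF1 is the main transcription factor of the heat shock response, and HSF2 is a related factor. The 6 groups held 3 biological replicates each, lettered a, b and c, giving 18 bead arrays of 47323 probes. Between 20743 and 22439 probes were detected per array (43.8% to 47.4%), and the number of arrays limits the precision of every value below. After filtering, 16676 features were tested, namely 12566 named genes and 4110 probes without a gene name. The comparisons ask which genes differ when HSF1 or HSF2 is targeted, at each day, and how the control cells differ between the days.

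The first 2 principal components held 33.9% and 30.3% of the variance, and along them the arrays lay apart by day and by letter b. On a score of the letter b difference, 5 of the 6 b arrays lay between 0.485 and 1.01. The a and c arrays lay between -0.38 and -0.141. The exception among the b arrays was HSF2 siRNA day 5 b, at -0.258. The score was fitted without the HSF2 siRNA day 5 arrays, so the parting of the other arrays on it is partly built in. The principal components were computed without the letters. Calls of the lists and genes named below that ended with letters a and c alone are therefore given, a choice made after the data were seen. Lists and single genes of the day contrast over all siRNA groups and of the averages over both days were not tested this way.

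**Figure D1:**
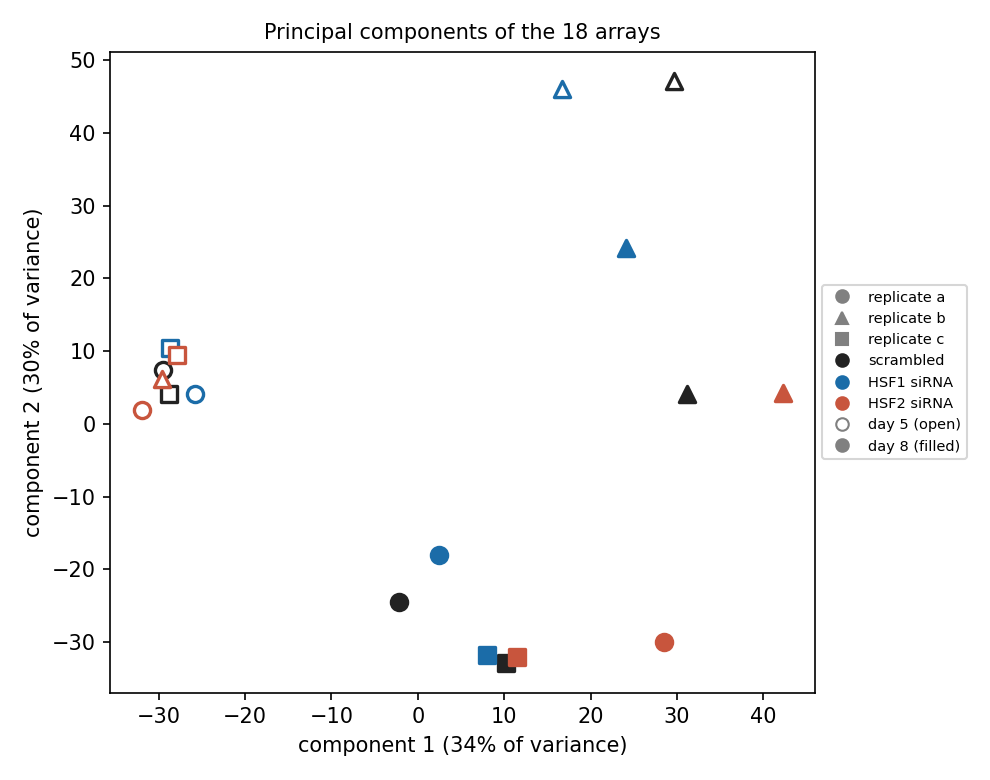
Each point is 1 of the 18 arrays, placed by its scores on components 1 and 2 of the normalized log2 values, with 33.9% and 30.3% of the variance; shape gives the replicate letter, color the siRNA, and open or filled the day. The b arrays lie apart from the a and c arrays of their day, except HSF2 siRNA day 5 b, which lies among the day 5 a and c arrays.

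The transcripts that the siRNAs target were not lower on every array of their groups. HSF2 (chromosome 6) had a mean log2 signal of 6.79 ± 0.55 (SD, n = 3) on the arrays labelled HSF2 siRNA at day 5, beside 7.04 ± 0.20 on scrambled arrays, and of 6.67 ± 0.55 beside 7.13 ± 0.06 at day 8. Against the scrambled array of the same day and letter, HSF2 differed by 0.35, -0.75 and -0.35 on arrays a, b and c at day 5, and by -0.80, -0.71 and 0.12 at day 8. HSF1 (chromosome 8) stood at 6.30 ± 0.45 beside 6.56 ± 0.30 on the arrays labelled HSF1 siRNA at day 5, and at 6.29 ± 0.36 beside 6.22 ± 0.11 at day 8. Its differences were 0.15, -1.11 and 0.19 at day 5 and 0.54, -0.21 and -0.10 at day 8. HSF2 lay below all 6 scrambled arrays on 3 of the 6 arrays labelled HSF2 siRNA and on 0 of those labelled HSF1 siRNA. HSF1 lay below all 6 scrambled arrays on 3 of the 6 arrays labelled HSF1 siRNA and on 2 of those labelled HSF2 siRNA. HSF1 siRNA day 8 b (6.135) and HSF2 siRNA day 8 a (6.124) did so only barely, the lowest scrambled value being 6.138. The array labelled HSF2 siRNA day 8 c had HSF2 at 7.31 and HSF1 at 5.786, the lowest HSF1 value of the 18, closely followed by HSF1 siRNA day 5 b at 5.791.

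In the limma model the target contrasts gave log2 differences of -0.25 (SE 0.255, adjusted p = 0.933) for HSF2 at day 5 and -0.46 (SE 0.255, adjusted p = 1) at day 8. HSF1 gave -0.26 (SE 0.231) at day 5 and 0.07 (SE 0.231) at day 8, both with adjusted p = 1. The sign of 3 of these values turned with the arrays used: HSF2 at day 5 was 0.05 without HSF2 siRNA day 5 b, HSF1 at day 8 was -0.13 without HSF1 siRNA day 8 a, and HSF1 at day 5 was 0.17 with letters a and c alone. Groups are therefore named by their labels throughout, and no direction given for them is a direction of measured silencing.

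**Figure D2:**
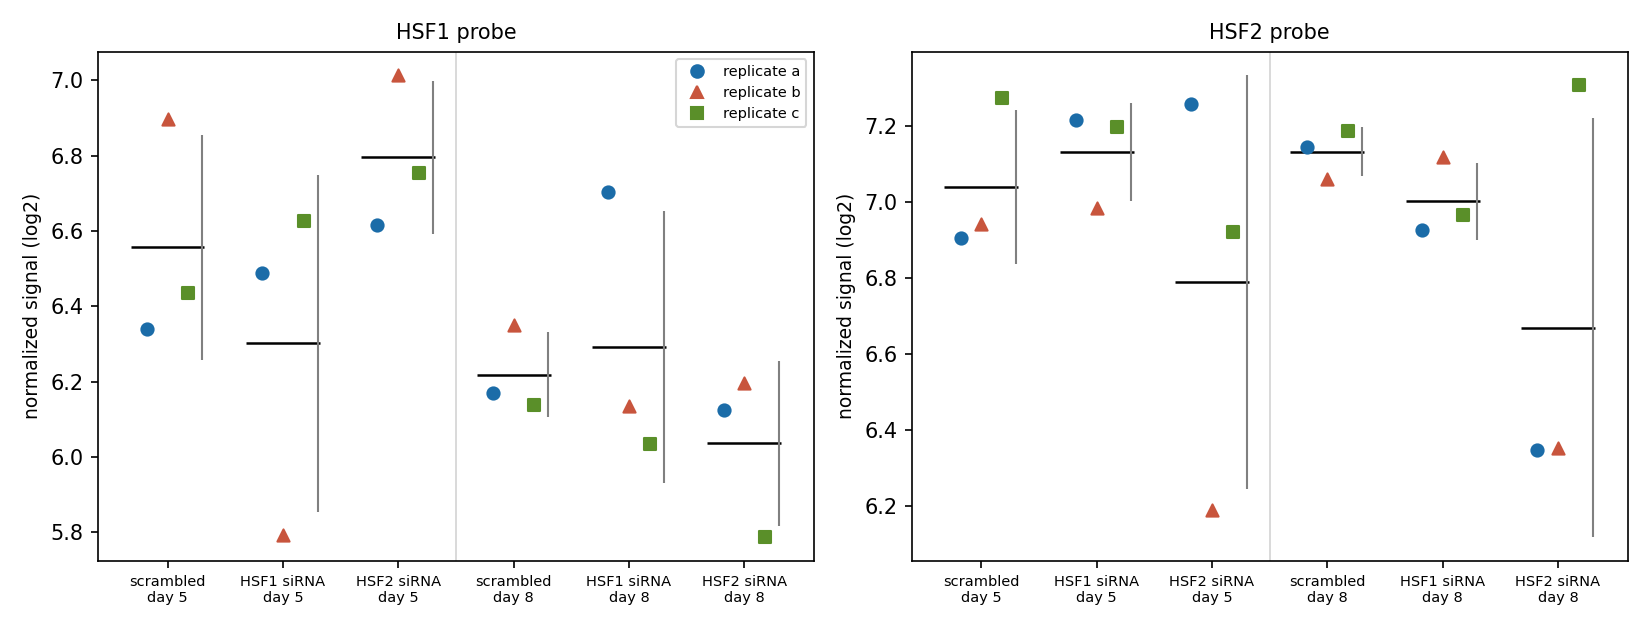
Normalized log2 signal of the HSF1 and HSF2 probes on each array by group, with the group mean (black line) and SD over 3 arrays (grey bar). HSF2 lies below all 6 scrambled arrays on 3 arrays labelled HSF2 siRNA, and HSF1 does so on 3 arrays labelled HSF1 siRNA and 2 labelled HSF2 siRNA. For HSF1 this holds only barely on HSF1 siRNA day 8 b and HSF2 siRNA day 8 a.

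Between day 5 and day 8, scrambled arrays showed higher interferon-response genes and lower DNA replication genes as sets. Neither set call held with an estimated correlation between genes (adjusted p = 0.201 and 0.228). Among single genes, HPGD, which breaks down prostaglandins, rose 9.35-fold (log2 3.23, SE 0.477), from 7.42 ± 0.25 to 10.65 ± 0.54 on the log2 scale (SD, n = 3). The adhesion molecule CEACAM6 rose by 2.84 (SE 0.485), the matrix glycoprotein SPARC by 2.57 (SE 0.513) and the hyaluronan-link protein HAPLN1 by 2.53 (SE 0.272). At day 5 CEACAM6 was detected on 2 of the 3 arrays and SPARC on 1 of the 3, so both values depend on the background. Their lowest log2 values under an alternative setting were 1.06 and 0.80. CIDEC, a lipid-droplet protein, was undetected at day 5 and, on the background-corrected scale, at least 4.49-fold higher at day 8; its log2 value was 0.77 in the authors' normalized table, where it did not pass. The ubiquitin ligase MARCHF4 fell by 2.09 (SE 0.32), a value that depends on the background, since 2 of the 3 day 8 arrays detected it (-0.72 in the authors' table). GKN2 fell by 1.83 (SE 0.445), the focal adhesion protein LPXN by 1.65 (SE 0.363) and the keratin KRT80 by 1.32 (SE 0.256). MPP4, undetected at day 8, was at least 2.40-fold lower on the background-corrected scale (log2 -0.36 in the authors' table).

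The interferon list had 12 of 41 measured members that rose and 25 adjusted over the list alone, with a mean log2 change of 0.86 (0.90, 0.93 and 0.76 for letters a, b and c). Its named members were IFITM1 (2.97, SE 0.53) and IFI27 (2.46, SE 0.504). In the G1/S and DNA replication list all 37 members had negative values with a mean of -0.52 (-0.55, -0.30 and -0.70). None passed over all genes and 19 did adjusted over the list alone, and the largest value was that of UHRF1 (-1.12, adjusted p = 0.0699), which maintains DNA methylation at replication. The G2/M list gave a mean of -0.30 with 36 of 41 members negative and 4 past the threshold adjusted over the list alone. The mitotic transcription factor FOXM1 stood at -0.84 (adjusted p = 0.0963). Of 28 TGF-beta and YAP targets, 3 fell, ID3 by 1.81 (SE 0.293) and ID1 by 1.01 (SE 0.206) among them, and the list mean was -0.30.

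Epithelial and lipid synthesis lists also ranked higher at day 8, with 1 member of each past the threshold. Both calls were lost with an estimated correlation (adjusted p = 0.511 and 0.487) and without scrambled day 5 a or day 8 b. In the list of epithelial junctions and keratins 1 of 28 members rose, KRT19 (1.08, SE 0.178), and 22 had positive values (mean 0.29). Of the 32 cholesterol and fatty acid genes TM7SF2, a sterol reductase, rose by 1.65 (SE 0.324), and 28 were positive (mean 0.30). The androgen and luminal prostate list had 3 of 14 members that rose, among them HOXB13 (1.19, SE 0.28) and NDRG1 (1.09, SE 0.271), and 1 that fell (mean 0.33). The 16 TRiC and mitochondrial chaperones were all negative (mean -0.30, 0 past the threshold), as were 30 of 33 proteasome genes (mean -0.18, 0 past it). The list of markers of other cell types, with 8 of 27 measured, had a mean of 0.37 and 1 member that rose, PECAM1 (1.09, SE 0.244). Its call was lost with an estimated correlation (adjusted p = 0.278), with no filter and without scrambled day 5 a, day 5 c or day 8 b. Other genes named by list were the basal keratin KRT15 (2.15, SE 0.346), ZYX (1.02, SE 0.205), SERPINE2 (0.92, SE 0.204), the chaperone DNAJB9 (0.88, SE 0.179) and the ERK phosphatase DUSP6 (0.83, SE 0.175), all of which rose. The protease MMP10 also rose (1.26, SE 0.239), from a mean of 4.77 at day 5, where 1 of 3 arrays detected it, so its value depends on the background (0.29 in the authors' table).

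The limma test called 298 features (203 up, 95 down), 262 of them named genes, and 159 changed more than 2-fold. The share that rose was 68.1%, 84.5% with scaling to equal medians and 55.5% in the authors' normalized table. With the replicate letter as a block, which the correlations between letters allow here, 1271 were called. The arrays did not overlap for 19.7% of features, where chance gives 10%. Camera, a test of each list against all other genes, passed 10 of the 23 lists (5 up, 5 down), with adjusted p = 3.87e-22 for the interferon list, 5.16e-14 for G1/S and 3.7e-06 for G2/M. These gave adjusted p = 0.201, 0.228 and 0.386 with an estimated correlation, and the other 7 gave 0.228 to 0.511, so none of the 10 held. Fry, which tests each list by itself, passed 5 of the 23. The basal list, at adjusted p = 0.0529, missed the threshold, and the mesenchymal list had a mean of -0.01 and a median of 0.05.

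Leaving out 1 array moved the count to 54 without scrambled day 5 a, 88 without day 5 c, and 137, 133 and 46 without day 8 a, b and c. The interferon, G1/S, G2/M and TRiC lists kept their calls in each leave-out. The others were lost without day 5 a, day 5 c or day 8 b, with adjusted p between 0.0503 and 0.275. Of the 25 named genes past the threshold, HPGD, HAPLN1 and MARCHF4 passed under each alternative setting in which they were tested, and the other 22 lost their call in at least 1. NDRG1 lost it in 12 of 17 settings, CIDEC and GKN2 in 10 of 16, LPXN and HOXB13 in 9 of 17, PECAM1 in 8 of 17 and SPARC in 7 of 16. With letters a and c alone, IFITM1, DNAJB9, ZYX and DUSP6 lost their call. Sizes depended on how the values were made: in the authors' table HAPLN1 was 1.15 (1.01 with every probe tested on its own), GKN2 -0.75, IFI27 1.22, KRT15 1.21, IFITM1 1.84, PECAM1 0.58 and DNAJB9 0.56, and KRT80 was -0.71 with every probe tested on its own.

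**Figure D3:**
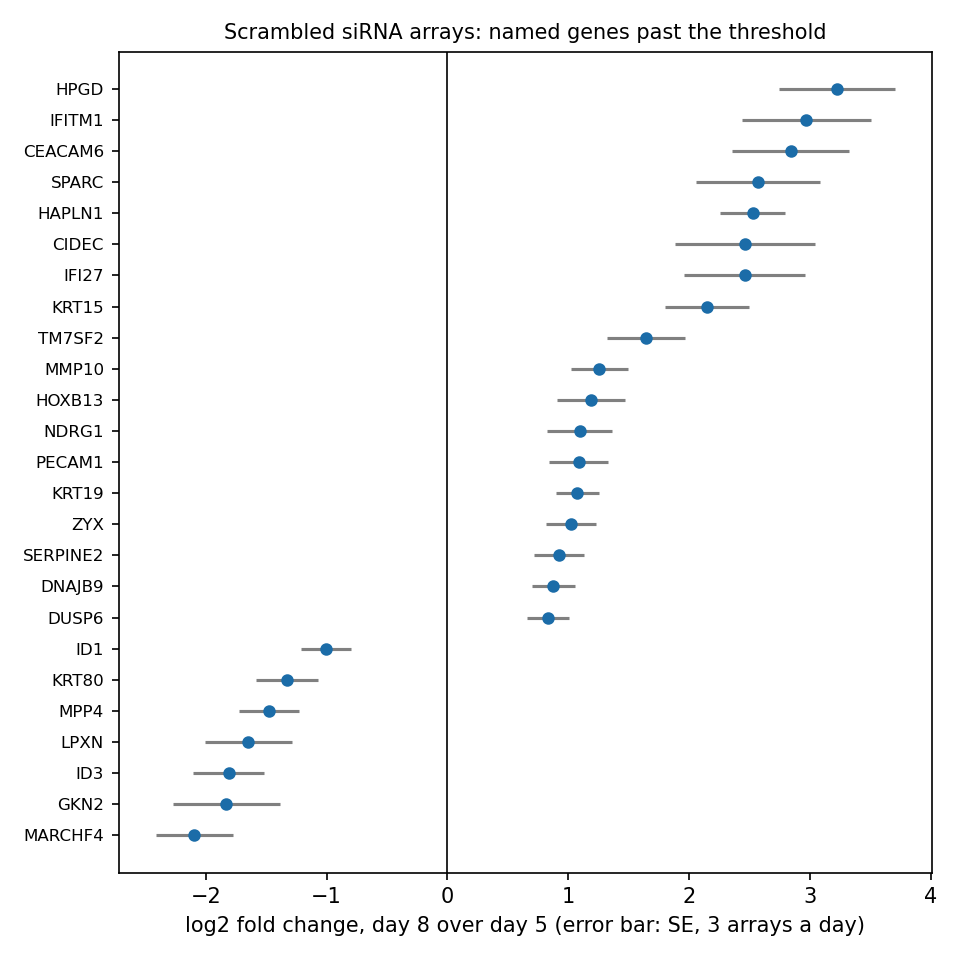
Log2 fold change of day 8 over day 5 on scrambled arrays for the 25 named genes past the threshold, with the standard error (grey bar, 3 arrays a day). Values run from 3.23 for HPGD to -2.09 for MARCHF4, and those of CIDEC, SPARC, CEACAM6 and MMP10 (not detected on all day 5 arrays) and of MPP4 and MARCHF4 (not detected on all day 8 arrays) depend on the background.

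At day 5, list differences between arrays labelled HSF2 siRNA and scrambled ones rested on the scrambled b array. No list call held without that array or with an estimated correlation, and no single gene passed the threshold. Among the members named for the largest value in their list were the laminin-binding integrin ITGB4 (-0.94, SE 0.43), the collagen COL6A3 (-0.89, SE 0.476), the protease ADAMTS1 (-0.70, SE 0.527), the cholesterol enzyme DHCR7 (-0.66, SE 0.461), the collagen hydroxylase P4HA2 (-0.59, SE 0.294) and the chaperone HYOU1 (-0.55, SE 0.343). Positive values were seen for the co-chaperone PTGES3 (0.58, SE 0.292), the centromere histone CENPA (0.48, SE 0.255), the replication factor GINS2 (0.47, SE 0.233) and the interferon-induced XAF1 (0.43, SE 0.148). As sets, integrins and laminins (mean -0.36, 29 of 31 negative), ER chaperones (-0.28, 19 of 19), matrix proteases (-0.27, 24 of 26) and cholesterol genes (-0.21, 24 of 32) ranked lower, and G2/M genes ranked higher (0.14, 32 of 41 positive). For letters a, b and c the integrin list differed by -0.01, -1.04 and -0.03 and the ER chaperone list by 0.04, -0.89 and 0.01.

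The limma test called 0 of 16676 features (smallest adjusted p = 0.933), with 352 at unadjusted p under 0.05 where chance gives 833.8. Here and in the siRNA contrasts below, the letter b difference is part of the spread that the fit without a block uses. Counts below chance therefore do not show that an siRNA had no effect. No overlap was seen for 8.46% of features, beside the 10% of chance. The 5 lists passed camera with adjusted p from 8.84e-06 (integrins) to 0.00386, and all gave adjusted p = 0.725 with an estimated correlation. None of the 5 passed without scrambled day 5 b (adjusted p 0.683 to 0.788), with letters a and c alone (0.592 to 0.988) or with array weights, and the protease list was also lost without HSF2 siRNA day 5 c. Heat shock proteins and co-chaperones, the textbook targets of both factors, had a mean of 0.11 with adjusted p = 0.147.

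At day 8, arrays labelled HSF2 siRNA showed lower sets of cell cycle genes and higher sets of hypoxia, adhesion and lipid genes than scrambled arrays, with no single gene past the threshold. None of these calls held with an estimated correlation (adjusted p = 0.304 to 0.673), and only that of G1/S passed in each leave-out of 1 array. The G1/S list had a mean of -0.23 (-0.49, -0.25 and 0.05 for letters a, b and c) with 33 of 37 members negative, and the G2/M list -0.22 (-0.59, -0.17 and 0.09) with 38 of 41 negative. Their largest members by value were the replication clamp loader RFC3 (-0.55, SE 0.247) and the hyaluronan receptor HMMR (-0.58, SE 0.231). Hypoxia and glycolysis genes had a mean of 0.20 (25 of 30 positive), with CA9, a hypoxia-induced carbonic anhydrase, at 0.74 (SE 0.409). The epithelial list had a mean of 0.18 (23 of 28 positive), with the epithelial transcription factor ELF3 at 0.53 (SE 0.296); the mean turned to -0.05 without scrambled day 8 a. Integrins had a mean of 0.17 (24 of 31 positive), with ITGB4 at 0.76 (SE 0.43). Cholesterol genes had a mean of 0.17 (29 of 32 positive) and ATF4 targets 0.17 (20 of 24 positive). Leaving out 1 array took the mean to as little as 0.01 for cholesterol, 0.04 for integrins, 0.09 for hypoxia, 0.10 for ATF4 and -0.06 for G2/M. Immediate early genes had a mean of 0.12 (22 of 29 positive), oxidative phosphorylation genes -0.14 (41 of 49 negative), proteasome genes -0.13 (28 of 33 negative) and ribosomal protein genes -0.09 (44 of 58 negative). Other values were -0.89 (SE 0.411) for the cytokine IL24, 0.55 (SE 0.322) for PMEPA1 and 0.52 for both HSPA2 (SE 0.191) and DUSP4 (SE 0.18), of which DUSP4 had opposite signs on its 2 probes.

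The limma test called 0 of 16676 features (smallest adjusted p = 1), with 364 at unadjusted p under 0.05 where chance gives 833.8, and 1042 with the replicate letter as a block (smallest adjusted p = 0.766). No overlap was seen for 6.64%, beside the 10% of chance. The 11 lists passed camera with adjusted p from 1.64e-08 (G1/S and G2/M) to 0.0124 (integrins). With an estimated correlation, adjusted p = 0.432 for G1/S and G2/M and 0.304 to 0.673 for the other 9. Only the G1/S list passed in each leave-out of 1 array (highest adjusted p = 0.0118). Without HSF2 siRNA day 8 a the G2/M, hypoxia and proteasome lists were lost; without b, epithelial, integrin, cholesterol and ribosomal; without c, ATF4, epithelial, hypoxia, immediate early, ribosomal and oxidative phosphorylation. Without scrambled day 8 a the epithelial, integrin, cholesterol, immediate early and proteasome lists were lost, and without scrambled day 8 c the integrin and ribosomal lists. The highest adjusted p of these lists in a leave-out ran from 0.107 to 0.797.

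Arrays labelled HSF1 siRNA had lower interferon-response genes as a set at both days. Neither call held with an estimated correlation (adjusted p = 0.941 at day 5 and 0.125 at day 8), the day 5 call was lost without HSF1 siRNA day 5 b, and letter a showed no lower mean at either day. At day 8 all 41 measured members of the list had negative values, with a mean of -0.40 (0.04, -0.70 and -0.54 for letters a, b and c). The largest was that of IFI27 (-1.36, SE 0.504). At day 5 the mean was -0.17 (0.01, -0.27 and -0.25), with 35 of 41 negative and IFI27 at -0.68 (SE 0.504). At day 8 cell cycle genes ranked higher, calls that held neither with an estimated correlation nor with letters a and c alone. The means were 0.13 for G1/S (0.19, 0.29 and -0.10 for letters a, b and c, and -0.0076 without HSF1 siRNA day 8 b; 30 of 37 positive, RRM2 at 0.47, SE 0.264) and 0.09 for G2/M (32 of 41 positive, the proliferation marker MKI67 at 0.44, SE 0.261). NF-kB targets also ranked higher (0.13, 20 of 25 positive, the chemokine CXCL5 at 0.64, SE 0.51), a call lost with an estimated correlation (adjusted p = 0.921), with no filter and with array weights. Other values at day 8 were -0.57 (SE 0.346) for KRT15, -0.49 (SE 0.513) for SPARC and 0.47 (SE 0.226) for the stress protein SESN2, detected on 1 of 3 scrambled arrays. At day 5 they were 0.59 (SE 0.298) for the YAP target ANKRD1, 0.55 (SE 0.398) for the tight junction protein CLDN1, -0.46 (SE 0.203) for TGFBI and -0.28 (SE 0.233) for the small heat shock protein HSPB1. Heat shock proteins and co-chaperones had means of -0.04 at day 5 (adjusted p = 0.531) and 0.00 at day 8 (adjusted p = 0.992).

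The limma test called 0 of 16676 features at either day (smallest adjusted p = 1), with 144 at unadjusted p under 0.05 at each day where chance gives 833.8, and 296 and 356 with the replicate letter as a block. No overlap was seen for 3.59% at day 5 and 4.04% at day 8, beside the 10% of chance. For interferon, camera gave adjusted p = 4.95e-07 at day 5 and 7.06e-26 at day 8, and adjusted p = 0.941 and 0.125 with an estimated correlation. The other day 8 lists had adjusted p = 0.000265 (G1/S), 0.0087 (G2/M) and 0.0239 (NF-kB), and 0.921 to 0.994 with an estimated correlation. The day 5 interferon call was lost without HSF1 siRNA day 5 b (adjusted p = 0.121), and the day 8 interferon call passed in each leave-out. G1/S was lost without scrambled day 8 c and without HSF1 siRNA day 8 a or b (up to 0.942), G2/M without scrambled day 8 c and HSF1 siRNA day 8 b (up to 0.276), and both with letters a and c alone (0.359). NF-kB was lost without scrambled day 8 a or c and HSF1 siRNA day 8 b or c (up to 0.552).

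**Figure D4:**
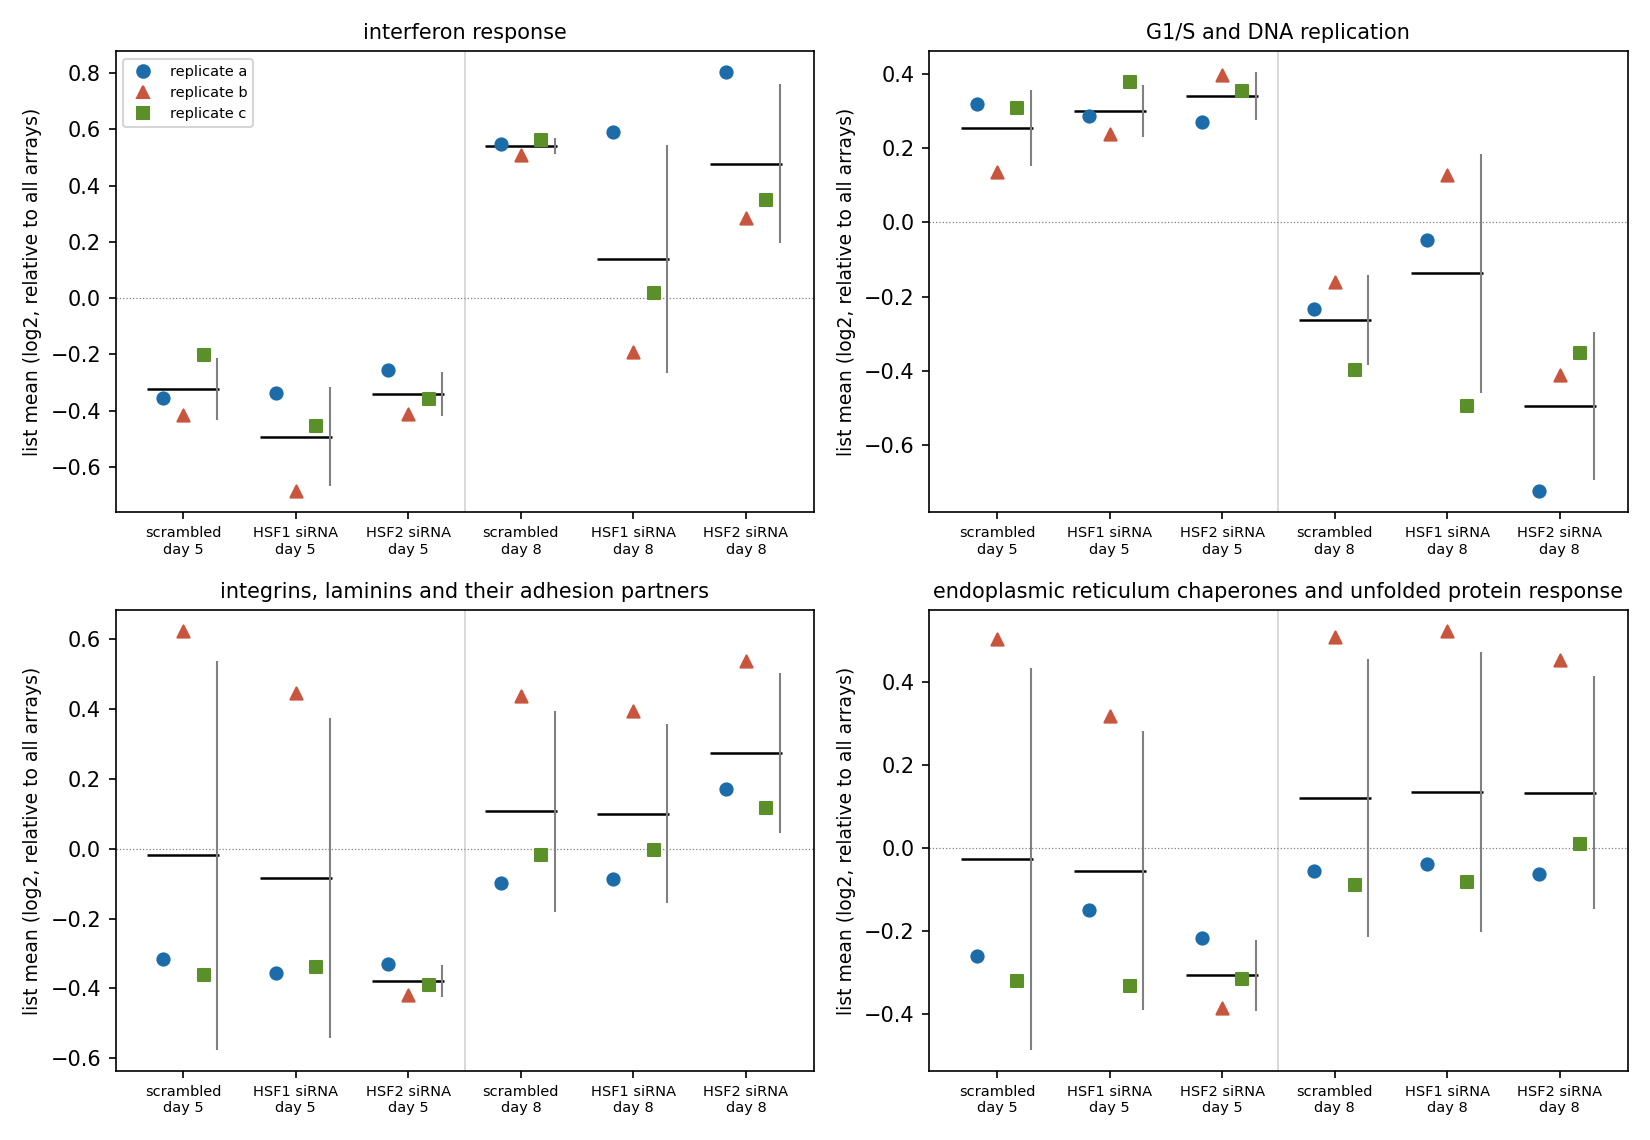
Mean log2 value of the members of 4 gene lists on each array, relative to the mean of all 18 arrays, by group, with the group mean (black line) and SD over 3 arrays (grey bar). Interferon genes are higher and G1/S genes lower at day 8, and the b arrays lie higher in integrins and ER chaperones except for HSF2 siRNA day 5 b.

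Set directly against each other at day 8, arrays labelled HSF2 siRNA had lower cell cycle sets and a higher interferon set than arrays labelled HSF1 siRNA. None of these calls held with an estimated correlation (adjusted p = 0.216 to 0.26). The G1/S list had a mean difference of -0.36 (35 of 37 negative), the G2/M list of -0.31 (41 of 41 negative) and NF-kB targets of -0.27 (20 of 25 negative). For letter c the G1/S list went the other way, with a higher mean on the array labelled HSF2 siRNA. Leaving out 1 array gave means of -0.54 to -0.22 for G1/S, -0.45 to -0.15 for G2/M and -0.38 to -0.09 for NF-kB targets. Interferon genes differed by 0.34 (36 of 41 positive) and epithelial genes by 0.20 (21 of 28 positive), the latter call being lost with letters a and c alone (mean 0.11, adjusted p = 0.158). At day 5 the integrin and protease lists both had a mean difference of -0.30, with letter b at -0.86 and -0.82, and the heat shock list one of 0.14 (19 of 28 positive). With letters a and c alone these became -0.01, -0.04 and 0.03, and the calls were lost (adjusted p = 0.959, 0.93 and 0.93).

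The limma test called 0 of 16676 features at day 5 and at day 8 (smallest adjusted p = 0.983 and 1), with 238 and 605 at unadjusted p under 0.05 where chance gives 833.8. With the replicate letter as a block, which the correlations between letters allow at day 8, 0 features passed there and 1432 had an unadjusted p under 0.05 (smallest adjusted p = 0.0979). No overlap was seen for 8.73% and 6.43%, beside the 10% of chance. Camera, applied to these contrasts after the data were seen, passed 7 lists at day 5 and 13 at day 8, among them G1/S (adjusted p = 1.5e-16), G2/M (1.34e-14) and interferon (1.07e-09) at day 8. With an estimated correlation these gave adjusted p = 0.216, 0.216 and 0.26, and none of the lists passed at either day. G1/S, G2/M and interferon at day 8 passed in each leave-out, and the other 10 did not, with epithelial genes lost without HSF1 siRNA day 8 a or HSF2 siRNA day 8 b or c (up to 0.664) and NF-kB targets without HSF2 siRNA day 8 a (0.197). At day 5 all 7 were lost in at least 1 leave-out, integrins and proteases without HSF1 siRNA day 5 b (0.834 and 0.964), and heat shock also without HSF2 siRNA day 5 c (up to 0.815).

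Across all genes, the effects under the HSF1 and HSF2 labels were set beside the correlation that shared control arrays give by themselves. Pearson's r across 16676 features, which are not independent replicates, was 0.414 at day 5 and 0.269 at day 8, beside 0.50 in simulated unchanged groups of independent arrays. That simulation takes no account of the letters, which pair these arrays except for HSF2 siRNA day 5, and with letters a and c alone r was 0.495 and 0.387. The covariances were 0.0141 and 0.00873 beside 0.0299 simulated, and 0 genes passed limma in both. Between day 5 and day 8, which share no arrays, r was 0.0996 for HSF1-labelled arrays and -0.322 for HSF2-labelled arrays, and the latter was 0.0255 with letters a and c alone. No single gene's difference between the days passed in limma, for either HSF2 (smallest adjusted p = 0.865, 642 features at unadjusted p under 0.05) or HSF1 (1, 116 features).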

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

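The list tests on day differences, the fit with letters a and c alone and the test of a different degree of HSF2 silencing were chosen after the results were seen.

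For 11 gene lists, the difference between arrays labelled HSF2 siRNA and scrambled arrays itself differed between the days (camera on the day 8 minus day 5 contrast, preset correlation). The mean log2 difference was 0.528 higher at day 8 for integrins and laminins (adjusted p = 5.85e-06), 0.386 for cholesterol genes (8.36e-05), 0.343 for matrix proteases (0.00431), 0.30 for hypoxia genes (0.000596), 0.293 for ER chaperones (0.0231) and 0.284 for ATF4 targets (0.00159). It was -0.364 for G2/M (1.16e-07), -0.319 for G1/S (5.85e-06), -0.212 for proteasome genes (0.00364), -0.180 for oxidative phosphorylation (0.00547) and -0.123 for ribosomal proteins (0.0351). With an estimated correlation none passed (adjusted p from 0.503 to 0.694). When 1 array at a time was left out, ATF4, integrins, G1/S, G2/M and cholesterol stayed past the threshold (up to 0.0487). ER chaperones were lost without scrambled day 5 b, HSF2 siRNA day 5 b, scrambled day 8 a or c or HSF2 siRNA day 8 b (up to 0.887), and proteases without scrambled day 5 b, scrambled day 8 c or HSF2 siRNA day 8 b (up to 0.349). Hypoxia (0.0914) and oxidative phosphorylation (0.201) were lost without HSF2 siRNA day 8 c, and proteasome genes without scrambled day 5 b (0.166). Ribosomal proteins were lost without scrambled day 5 b, HSF2 siRNA day 5 a, scrambled day 8 a or c or HSF2 siRNA day 8 b or c (up to 0.351). Under the HSF1 label the interferon list differed by -0.232 (adjusted p = 0.000293, and 0.977 with an estimated correlation). It was lost with letters a and c alone (0.472) and without HSF1 siRNA day 5 a, day 8 b or day 8 c (up to 0.455).

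Background correction and normalization are argued against as the source of the HSF2 pattern, since under 3 other ways of making the values, at least 10 of the 11 lists stayed past the threshold in the same direction. The b arrays could account for part of it, since with letters a and c alone 7 of the 11 lists stayed (ATF4, integrins, proteases, G1/S, G2/M, hypoxia and oxidative phosphorylation), with the integrin difference at 0.22 in place of 0.53. A different degree of silencing at the 2 days cannot be told apart from no change, because the HSF2 difference changed by -0.212 (SE 0.361, 95% interval -0.97 to 0.55). A biological change of the HSF2 effect with time stays open and rests on 3 arrays a group.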

How the results depend on the processing

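Letters a and c alone and the day contrasts in siRNA-treated arrays were chosen after seeing the data. Under alternatives that used all arrays or letters a and c, 258 summary values stayed within their limit, counts that remained 0 among them. For HSF1 and HSF2 the limit was direction and side of the threshold. Of single genes, 1434 values kept direction and side, including genes past the threshold in neither fit. Another 48 lost a call, 21 gained one and 8 turned in direction. When 1 array was left out, 80 single gene values of the scrambled day contrast lost a call, 2 gained one and 140 kept their side. Of the summary values under alternatives that used all arrays or letters a and c, 20 moved by more than their limit. That limit was 1.5 times for a count and the spread for a correlation. Another 8 counts fell to 0 and 4 values turned in direction. When 1 array was left out, 29 summary values moved by more than their limit, 1 count fell to 0, 2 values turned in direction and 142 stayed. The 10 contrasts of or between siRNAs with 0 genes in limma kept that count in each setting run. Their lowest adjusted p was 0.0523 (HSF2 siRNA averaged over both days, no filter), and 0.243 in the 4 planned contrasts with scrambled arrays, which had up to 1485 features at unadjusted p under 0.05 (HSF2 siRNA day 5, replicate block). Slide as a block was not run because the files give no slide, and the similarity among genes past the threshold has no value because none passed. Signal over background limits CIDEC and MPP4, undetected at 1 day, SPARC, MMP10 and CEACAM6, not detected on all day 5 arrays, and MARCHF4, not detected on all day 8 arrays. The sizes of other named values also shrank by more than 1.5 times under an alternative, among them HAPLN1 (to 1.01), GKN2 (-0.75), IFI27 (1.22) and KRT15 (1.21). The cause was not tested for these sizes or any value below, except where fewer arrays enter. With an estimated correlation 0 lists passed in each of the 4 siRNA contrasts and the scrambled day contrast. Scaling to equal medians gave 12 lists for HSF2 siRNA day 5. Tests of single probes turned DUSP4 (HSF2, day 8) to -0.051, RPL37 (HSF1, day 5) to -0.10 and PSMC6 (HSF1, day 8) to 0.10. With only the arrays compared, 61 genes and 16 lists passed in the scrambled day contrast, and 0 genes between days in HSF1 siRNA arrays. The replicate block gave 1271 genes between days in scrambled arrays, 597 in HSF1 and 4136 in HSF2 siRNA arrays, with the pairing of letters checked for scrambled arrays only. Array weights gave 1944 genes and 16 lists (scrambled), 433 (HSF1 siRNA days), 3337 (HSF2 siRNA days), 5934 (all groups), 0 lists for HSF2 and 2 for HSF1 siRNA at day 5, and a log2 value of 0.076 for HSF1 (HSF1 siRNA, day 5).

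With letters a and c alone, 203 genes passed between days in HSF1 siRNA arrays, and 0 lists for HSF2 day 5, 2 for HSF1 day 5 and 2 for HSF1 day 8. At day 5, HSF2 was then 0.00034, CXCL1 0.087, FOSL1 -0.045 and DSC3 0.013 under the HSF2 label, and HSF1 0.17, SERPINB2 -0.078 and TMPRSS2 -0.013 under the HSF1 label. The HSF1 and HSF2 effects correlated with r = 0.495 (day 5) and 0.387 (day 8), and the days with 0.0255 (HSF2) and 0.0582 (HSF1). The day 8 value was 0.213 in the authors' table and 0.314 without a filter. Leaving out 1 array gave 46 to 303 genes (scrambled days), 6 to 234 (HSF1 siRNA days), 1029 to 2224 (HSF2 siRNA days), 0 to 8 lists (HSF2 day 5), 6 to 13 (HSF2 day 8), 2 to 8 (HSF1 day 5), 3 to 7 (HSF1 day 8) and 4 to 17 (scrambled), HSF2 between -0.48 and 0.050 (day 5) and HSF1 between -0.13 and 0.20 (day 8).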

Other observations

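The contrasts over all siRNA groups, the averages over both days, the fit with letters a and c alone, and the tests of an exchanged array, of probe background, of exchanged labels and of recovery were chosen after the results were seen.

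Taken over all 3 siRNA groups, the adhesion, protease, ER chaperone and ATF4 lists ranked higher at day 8 than at day 5 and the replication list lower. None of these calls held with an estimated correlation (adjusted p from 0.139 to 0.419). The integrin, protease and ER chaperone means were 0.65, 0.53 and 0.44 in HSF2 siRNA arrays and 0.18, 0.16 and 0.19 in HSF1 siRNA arrays. None of these 3 lists passed in scrambled arrays, and all were higher in b arrays. The HSF2 siRNA b array stood apart at day 8 and not at day 5, so day and letter b are partly mixed here. Lists and genes of this contrast were not tested with letters a and c alone. Its SE and p-values take the arrays of a day as independent, although letters were shared between siRNA groups, so they may be too small. The integrin subunit ITGB4, part of the laminin receptor of hemidesmosomes, rose by 1.66 (log2, SE 0.248), the collagen receptor subunit ITGA1 by 1.31 (SE 0.25) and the collagenase MMP1 by 1.39 (SE 0.255). TMPRSS2, a serine protease of luminal prostate cells, rose by 1.49 (SE 0.322) and the epithelial transcription factor ELF3 by 1.23 (SE 0.171). Of 24 ATF4 targets 8 rose, DDIT4 (1.73, SE 0.229) among them, and 1 fell, ATF5 (-0.83, SE 0.142). Of 19 ER chaperone and unfolded protein genes 5 rose, with DDIT3 (0.89, SE 0.136) and XBP1 (0.71, SE 0.111) among them, while of 28 heat shock genes 3 rose and 5 fell. SPARC (2.59, SE 0.296) and HAPLN1 (2.54, SE 0.157) rose, and THBS1 fell by 1.71 (SE 0.293). The sizes of SPARC and HAPLN1 depend on how the values were made: in the scrambled day contrast an alternative setting brought them down to 0.80 and 1.01. Of 24 mesenchymal genes 3 rose and 4 fell (mean 0.09). Falls were also seen for the YAP target ANKRD1 by 1.11 (SE 0.172) and the receptor kinase AXL by 0.89 (SE 0.18). Replication genes fell, among them UHRF1 (-1.10, SE 0.173), CDT1 (-1.09, SE 0.194) and RRM2 (-1.06, SE 0.153).

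In the lists, 27 of 41 interferon genes rose, 33 of 37 G1/S genes and 25 of 41 G2/M genes fell, and 13 of 32 cholesterol genes rose. Chaperones of TRiC and mitochondria fell in 10 of 16 and proteasome genes in 10 of 33. Of 28 TGF-beta and YAP targets 9 fell and 2 rose, while of 28 epithelial genes 9 rose and 1 fell. Of the 8 measured markers of other cell types 4 rose, among them PECAM1 (1.11), CD68 (0.68) and KDR (0.32), and 0 fell (mean 0.40, adjusted p = 0.0041, and 0.174 with an estimated correlation). Camera gave adjusted p = 2.68e-17 for interferon and for G1/S, and 0.139 for each with an estimated correlation. In all, limma called 3841 features (1858 up, 1983 down), and 5742 with the replicate letter as a block. Both counts may be too high, since arrays of 1 letter correlated between siRNA groups within a day. For HSF1 siRNA against scrambled arrays r was 0.663 to 0.820 at day 5 and 0.435 to 0.763 at day 8. A block common to both days does not remove what a letter shares within 1 day. Between days, 64 features passed in HSF1 siRNA arrays and 2091 in HSF2 siRNA arrays, which does not show that the arms differ, since no gene's difference in day change between an siRNA and scrambled arrays passed the threshold. With the replicate letter as a block these counts were 597 and 4136, with array weights 433 and 3337, and the HSF1 siRNA count was 203 with letters a and c alone and 0 with only the arrays compared. Whether letters pair was not checked in these contrasts or over all groups. The HSF2 siRNA b array scored -0.258 on the b difference at day 5 and 0.601 at day 8. The HSF1 siRNA count was 38 without HSF1 siRNA day 5 b, 6 without day 5 c, and 6, 234 and 10 without day 8 a, b and c. The HSF2 siRNA count was 1219, 1029 and 1095 without HSF2 siRNA day 5 a, b and c and 1106 without day 8 a. Averaged over both days, 0 features passed limma for either siRNA, with 226 (HSF2) and 178 (HSF1) at unadjusted p under 0.05, and the interferon list had a mean of -0.29 under the HSF1 label (adjusted p = 3.52e-27, and 0.106 with an estimated correlation).

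The arrays of letter b stood apart: against a and c within groups, with HSF2 siRNA day 5 included, limma called 5800 features (2884 higher, 2916 lower in b). Only the score of the b difference was taken without HSF2 siRNA day 5. Proteases (0.54), integrins (0.50), ER chaperones (0.48), epithelial genes (0.40) and cholesterol genes (0.36) were higher in b as lists, and interferon (-0.23), heat shock (-0.19) and ribosomal genes (-0.13) lower (adjusted p up to 0.0176, and from 0.463 with an estimated correlation). The median absolute log2 difference was 0.264 in the brightest genes and 0.192 in the others, 1.37 times as large in the brightest. The offset of 16 added before log2 shrinks the differences of dim genes, which favors such a ratio whatever the cause. The ratio therefore cannot decide whether background or weak signal made the b difference, and this stays open. A larger share of mRNAs of membrane and secreted proteins is a candidate explanation: SLC and TMEM genes lay 0.514 (log2) above MRPL, EIF and POLR genes. An exchange of HSF2 siRNA day 5 b with an a or c array is argued against by the a and c scores. These reach -0.141 at most, where the other 5 b arrays start at 0.485. It is not excluded, since most of these arrays also served to fit the score. HSF2 siRNA day 5 a and c, outside the fit, scored -0.344 and -0.196. A single wrong label or a sample handled apart from its letter stays open, and no biological explanation was tested.

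The target was not lower on each array of its group. An undetected probe is excluded, since the highest detection p of both probes on scrambled arrays was 0.0013. Detection does not show how well a probe reports silencing, and each target was read by a single probe. Scrambled signals before background correction were 101 to 152 for HSF1 and 155 to 199 for HSF2. The medians of undetected probes were 45.6 to 54.0, so a probe that reports falls poorly stays open. An exchange of labels between an HSF1 siRNA array and an HSF2 siRNA array on which HSF2 was lowered is argued against for a lowering of the size seen. Arrays labelled HSF2 siRNA on which HSF2 was lowered had it at 6.19 to 6.35. On arrays labelled HSF1 siRNA its lowest value was 6.93, and 0 of them lay below all 6 scrambled arrays. An exchange with a weaker lowering stays open, since day 8 a and c (6.93 and 6.96) lay below the scrambled arrays of day 8 (7.06 to 7.19). An exchange that involves an HSF2 siRNA array on which HSF2 was not lowered also stays open: 2 arrays labelled HSF2 siRNA had HSF1 below all 6 scrambled arrays, and 1 of them, day 8 c, had HSF2 at 7.31, above all 6 scrambled arrays. The other, day 8 a, had HSF1 at 6.124, barely below the lowest scrambled value of 6.138. Such an exchange cannot be told apart from uneven silencing, because HSF2 was lowered on 3 of the 6 arrays labelled HSF2 siRNA and a partner need not show it. Recovery of the target with time cannot be told apart from no change: from day 5 to day 8 the HSF1 difference moved by 0.328 (SE 0.327, 95% interval -0.36 to 1.02), and the HSF2 difference by -0.212, away from recovery (SE 0.361, -0.97 to 0.55). A single wrong label, silencing that had ended by day 5 and uneven transfection stay open.

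Splits of the same arrays into other groups were counted for each contrast. For the 4 siRNA contrasts and both HSF2 against HSF1 contrasts the 10 splits are too few for a share under 0.05: the real count was 0 and the highest other 0, except 2 for HSF2 against HSF1 at day 8. All 10 give as many as a real 0 by construction. The same holds for the day contrasts in scrambled (real 298, highest other 0), HSF1 siRNA (64, 0) and HSF2 siRNA arrays (2091, 0), where 1 of the 10 splits, the real one, gave as many. Over all 3 groups, 1 of 100 splits, the real one, gave as many (3841, highest other 3100). Other splits that part all pairs gave at most 0. This argues against chance but does not exclude it, since the other splits were a random draw and 1 of 100 is the smallest share possible. Each siRNA group was also split by itself, although letters were shared between the groups. The 3100 show that another grouping of these arrays can also call many features. For the day difference and the average over both days of either siRNA the real count was 0, which all 100 splits reach whatever the data, so these counts say nothing about chance. The highest other count was 0 for HSF2. For HSF1 it was 1538, and at most 0 among other splits that part all pairs. So high a count can come from a structure of the samples other than the siRNA, but which arrays made that split was not examined.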
